A study of Saccharomyces cerevisiae with 327 samples.

How the data were processed

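Binding of the yeast transcription factor Gln3 was profiled by ChEC-seq, in which a DNA-binding protein is fused to micrococcal nuclease (MNase) and the released DNA ends are sequenced. The series holds 327 libraries, submitted as a first set of 186 and a second set of 141; 2 were left unassigned and the others form 130 groups. Each library came from a strain in the BY4741 background with a full-length, shortened or otherwise altered Gln3 fused to MNase, or, in part of the second set, with a Hap2 fusion. Per the labels' protocols, cells were grown in synthetic medium with glucose to OD 4, or grown exponentially and moved to another medium for 60 min. DNA was extracted with phenol and chloroform, per the labels' protocols. Groups hold between 1 and 6 libraries: 11 groups hold 1, 65 hold 2, 41 hold 3, 8 hold 4, 1 holds 5 and 4 hold 6.

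Each deposited file holds 1 column of whole-number counts, which per the labels and the files' lengths are read-end counts at each of the 12157105 bases of the R64 genome, with no normalization. Reads were processed with bcl2fastq, cutadapt, Bowtie2 and bedtools, per the submitters' processing notes; versions, settings and any removal of duplicates or of multiply mapped reads are not given in the sources used here. All 327 totals were even, as they are when each fragment adds a pair of ends, so the 2 ends of a fragment are not independent counts. Totals ran from 47862 to 18533778 read ends per library, with a median of 1676994.

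Read ends were summed over promoters, defined from the R64 annotation of 6002 protein-coding genes as up to 700 bp upstream of the start codon, clipped at the neighbouring coding sequence. Stretches under 100 bp and mitochondrial ones were left out, and 1385 divergent gene pairs whose stretches met shared 1 promoter, written with both names. This gave 4424 promoters of a median 451 bp, together 17.84% of the nuclear genome. Promoters held 8.81% to 50.1% of a library's read ends, the mitochondrial genome 2.23% to 60.6% and the ribosomal DNA 3.70% to 34.9%. Promoter read ends per library ran from 17390 to 4282940 with a median of 522879, and 15 libraries had under 100000. No genome sequence was used here, so motif occurrences were not counted. Near-identical copies such as ASP3-1 to ASP3-4 may share reads, and their separate values are uncertain.

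The 2 unassigned libraries have a title that differs from their genotype or growth label in a way that leaves their group open, and 8 further groups with 12 libraries entered no comparison. The main comparisons (16 of 112), the gene lists, the thresholds, the alternatives and the rule for naming promoters were fixed before the data were examined. Replicates carry letters or numbers, and no label says that they came from separate cultures, so each p measures the spread between these samples, which may be technical. Across 306 replicate pairs Pearson's r of log2 promoter values over promoters ran from 0.343 to 0.982 with a median of 0.852. No pair held identical promoter counts, and every library was counted as 1 sample. The smallest chi-square per degree of freedom, taken on read ends, was 2.19, between the libraries of Gln3(481-730)D. Since each fragment adds a pair of ends, repeat runs of 1 library could also give a value near 2. The closest pairs may therefore be the same sample sequenced again.

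Differential binding was tested two-sided with edgeR 4.0.16 (R 4.3.3) quasi-likelihood models, 1 model per family of related groups, with TMM scaling and the filterByExpr low-count filter. A promoter was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 fold change was at least 1 in size. CPM values are edgeR's counts of promoter read ends after scaling to a common total, given as the mean ± SD over libraries, and fold changes are log2 ± standard error. Promoters named are the 10 with the largest called changes in each direction (3 in the smaller series) with a mean of at least 100 CPM and no overlap between the libraries of the sides, edited loci left out, together with members of the fixed lists; every coordinate is in R64. The lists, with the promoters measured, were nitrogen catabolite repression (52), respiration genes bound by the CCAAT-box complex (42), amino acid permeases induced by the SPS sensor (10), amino acid synthesis under Gcn4 (47), Msn2 stress genes (27), retrograde-response genes (7), glycolysis (16) and ribosomal protein genes (53). In the gat1 deletion the nitrogen list counted 51, since its own GAT1 promoter was edited. The lists overlap, for example at AGP1/KCC4. List shifts were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 8 lists, and again with an estimated correlation. In the 16 main comparisons 73 list calls were made at the preset value, and 27 of them held with the estimated correlation; a list call given without a value for that correlation is one of these.

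Shares of promoter read ends at a list need no scaling factor between libraries, but as sums they rest most on the strongest promoters. They were compared with two-sided exact permutation tests where at least 3 libraries stood on each side, 26 comparisons per readout, adjusted by Benjamini-Hochberg. Differences between effects were tested as interaction terms in edgeR. The alternatives were RLE scaling, library size only, DESeq2 1.42.0, no low-count filter, no fold threshold, a 400 bp window, a cap of 10 read ends per base, libraries of at least 100000 promoter read ends, a model of the compared groups only, the replicate label as a block, and each library left out in turn. A side with 1 library, by design or after leaving out, was assumed to vary like the other groups of its model, since it has no spread of its own. Scripts ran under Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

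The model was tested on simulated counts with 100 promoters changed 2-fold and 100 changed 4-fold. With the sizes and depths of the ure2 deletion in Gln3(1-480), 3 libraries a side, it called 7% of the former and 54% of the latter, with 2 unchanged promoters called. For Gln3(272-730) against intact Gln3, 2 a side, it called 3% and 37% with 0 unchanged. For the K. lactis orthologue, 3 against 2, it called 0% and 11% with 1 unchanged, and for the hap2 deletion in Gln3(1-502+506-730), 6 against 3, it called 10% and 54% with 3 unchanged. Small counts of called promoters in these designs therefore leave 2-fold changes mostly undetected. Deviations of libraries with the same replicate label were correlated in 73 pairs of groups, counted per comparison. Among pairs of groups with 3 or more shared labels none had every correlation above 0.1, so the labels were not treated as pairing samples; some pairs with 2 shared labels, as in Gln3(531-730)A and D (0.2408), lay above it.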

Results

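Gln3 is a GATA-type activator of nitrogen catabolic genes in budding yeast, and the labels describe a large set of strains in which parts of it outside the DNA-binding domain were removed, replaced or altered and its binding was mapped by ChEC-seq. Of the 327 libraries 2 were left unassigned, and the others fall into 130 groups. The first set, of 186 libraries, holds intact Gln3 (2 libraries), truncations from either end with and without a ure2 deletion, strains lacking HAP2, GAT1, GCN4 or DAL81, a change of medium, series labelled A and D along the protein, and orthologues from other yeasts. The second set, of 141 libraries, holds variants of residues 101-280 and 481-580, deletions of other regulators, and Hap2 fusions. It has no intact Gln3 in an otherwise unaltered strain, so the strains labelled stp1 and stp2 deletion (4 libraries pooled) served there as the control. Library totals ran from 47862 to 18533778 read ends, and promoter read ends, on which every value rests, from 17390 to 4282940. Values of comparisons that use the same control libraries share that control's error.

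The deleted genes were examined first. Read ends per base over the coding sequence, relative to the mean over the nuclear genome, were at most 0.191 for URE2 in the 38 libraries labelled as its deletion, where at most 12 read ends fell, against a median of 0.353 in the others. They were at most 0.036 for HAP2 in 22 libraries, 0.0243 for GAT1, 0.0776 for DAL81, 0.0834 for GCN4, 0.0664 for RTG1, 0.035 for RTG3, 0.0043 for GLN3 and 0.0231 for STP2, and 0 for HAP3 and HAP5. Among libraries not labelled as the deletion, the lowest value was 0 for each of these genes except GAT1 (0.413). Low coverage alone therefore does not mark a deletion. STP1 kept 0.187 to 0.227 in the libraries labelled stp1 deletion, against a median of 0.368 elsewhere, and these are named by their label throughout.

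Gln3(1-304+341-730) lacks the stretch that holds the GATA-type zinc finger, and its comparison with intact Gln3 asks where binding needs that domain. Signal fell at promoters of nitrogen genes, such as DAL1/DAL4 (allantoin breakdown and uptake, −2.66 ± 0.404 on the log2 scale, from 499 ± 171 to 78.2 ± 7.09 CPM, adjusted p = 7.77e-06, n = 3 and 2). It fell at NPR1, a kinase that controls permeases, (−2.84 ± 0.425, 7.51e-06), at DAL7 (−2.71 ± 0.403), at GZF3, a GATA-family repressor, (−2.63 ± 0.475, 0.000131), and at the GABA permease promoter UGA4 (−2.25 ± 0.354). It rose at YHR033W (VIII, 175090 to 175547, R64; 3.68 ± 0.569, 1.03e-05), the stress gene HSP26 (2.94 ± 0.517, from 510 ± 27.8 to 3910 ± 1582 CPM), and at the permease promoters BAP2 (2.87 ± 0.452, from 2155 ± 445 to 15738 ± 1887 CPM) and GNP1/SMT3 (2.86 ± 0.464). Of the 52 nitrogen promoters 18 fell, among them MEP1/YGR121W-A (ammonium permease, −1.96), DUR12/YBR209W (urea breakdown, −1.80) and GLN1 (glutamine synthetase, −1.22), and 3 rose, among them DIF1/CAR2 (2.47). Adjusted over the list alone these counts were 19 and 5, and the camera adjusted p was 4.46e-08. All other calls of lists were higher: 14 of 27 Msn2 stress promoters (24 adjusted over the list alone; 2.26e-19), such as HSP12/YFL015C (3.02 ± 0.889, 0.0275), and 11 of 42 respiratory promoters (19; 3.72e-14), such as MDH1 (2.13). So were 7 of 16 glycolytic ones (9; 1.05e-09), such as TDH3 (2.08), and 6 of 7 retrograde-response promoters (8.25e-06), such as CIT2 (peroxisomal citrate synthase, 1.92). Amino acid permeases were higher at 6 of 10 (7; 3.07e-10), such as TAT1 (2.47). The amino acid synthesis list (5 of 47 higher) and the ribosomal protein list (0 of 53) gave adjusted p of 0.0753 and 0.245. In all, 235 promoters rose and 72 fell of 4422 tested. With RLE scaling, which moved the median of all promoters to −0.25 from −0.12, 204 rose and 94 fell. With library size only (median −0.71) 88 rose and 213 fell, so the balance between directions rests on the scaling. With the cap on read ends per base 126 rose and 74 fell, and with only the compared groups 497 were called. The count of 307 fell to 203 and 176 without replicate A or B of the deletion, and to 88 and 54 without replicate 1 or 2 of intact Gln3. Of the promoters named, DUR12/YBR209W was not called without intact replicate 1, TDH3 and DIF1/CAR2 without intact replicate 2, GLN1, MDH1, CIT2 and HSP12/YFL015C without either, CIT2 without replicate A of the deletion, HSP12/YFL015C without its replicate B, and BAP2, GNP1/SMT3, TAT1, GLN1 and CIT2 with the cap.

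The C-terminal truncations ask which residues outside the zinc finger direct Gln3 to each kind of promoter. Gln3(1-480), which ends well after the zinc finger, lost signal at promoters of mitochondrial respiration: at COX5A (a subunit of cytochrome c oxidase; XIV, 531412 to 531724, R64) signal fell from 981 ± 88.2 to 64.6 ± 15.3 CPM (−3.92 ± 0.569, adjusted p = 9.18e-07, n = 3 and 2). It fell at COX13 (−3.59 ± 0.433, 1.28e-08), at SDH3 (succinate dehydrogenase, −3.54 ± 0.486, 3.48e-07) and at ATP19 (ATP synthase, −3.88 ± 0.708, 0.000128). In the fixed list 28 of 42 respiratory promoters fell and 0 rose (32 and 1 adjusted over the list alone; camera 3.30e-45). Of the 10 amino acid permeases 7 fell (8 adjusted over the list alone; 1.25e-17), including AGP1/KCC4 (−2.77), BAP3/HEM12 (−3.19) and GNP1/SMT3 (−2.71). Nitrogen promoters went both ways: 15 rose, such as DAL1/DAL4 (3.04 ± 0.443, from 499 ± 171 to 4080 ± 1155 CPM) and UGA4 (2.40 ± 0.379), and 5 fell, such as MEP3 (−2.73). That list gave 22 and 7 adjusted over the list alone and a camera adjusted p of 6.82e-05, with adjusted p = 0.275 with an estimated correlation. The amino acid synthesis list (1 higher and 4 lower, with NOC4/ASN1 at −3.05; 0.0256) and the stress list (1 higher; 0.0127) were called at the preset correlation, with adjusted p = 0.275 and 0.484 with an estimated correlation, and glycolysis (0.0523), the retrograde response (0.575) and ribosomal protein genes (0.921) were not. In all 105 promoters rose and 99 fell. With RLE scaling 80 rose and 122 fell, with the median of all promoters at −0.24 in place of −0.08, and DESeq2 called 326. Without replicate 1 of intact Gln3 28 rose and 58 fell, and without replicate 2 33 rose and 69 fell.

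Gln3(1-580) still carries residues 481-580, and the comparison of Gln3(1-480) with it isolates them. Respiratory promoters lost signal: TIM11 (ATP synthase) fell from 2444 ± 553 to 136 ± 23.2 CPM (−4.18 ± 0.479, adjusted p = 1.36e-09, n = 3 and 3). Signal also fell at ATP3 (−3.73 ± 0.342, 4.78e-13), COX13 (−3.71 ± 0.417, 1.02e-09), COX5A (−4.51 ± 0.559, 2.00e-08), COX8 (−3.98 ± 0.547, 2.41e-07) and SEF1 (−4.04 ± 0.766). In the respiratory list 28 of 42 fell and none rose (33 and 0 adjusted over the list alone; camera 9.70e-75), with QCR6 (−3.22), COX4 (−3.07) and SDH3 (−2.88) among them. Of the nitrogen promoters 4 fell, including UGA3/GLT1 (glutamate synthase, −2.90) and MEP1/YGR121W-A (−1.69), and the list as a whole was not called (0.727); the permeases had 0 calls (0.435). IDH2 (−2.02) was the 1 retrograde-response promoter that fell (3 adjusted over the list alone; 0.0380), and the ribosomal protein list was also called (0.0380), with adjusted p = 0.411 and 0.597 with an estimated correlation. In all 81 promoters fell and 10 rose; of those higher, YOR316C-A (1.46 ± 0.320, 0.00183) stayed called with each library left out. The rise of the others was less firm: without replicate B of Gln3(1-580) 88 rose and 81 fell, without replicate C 1 rose and 57 fell, and with only the compared groups 1 rose and 69 fell. UGA3/GLT1 was not called without Gln3(1-580) replicate C, nor COX4 with the 400 bp window. The median of all promoters was 0.05, and 0.15 with library size only. The share of promoter read ends at the respiratory list was 1.12 ± 0.0488% in Gln3(1-480) and 4.23 ± 0.710% in Gln3(1-580) (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 allows; 0.124 after adjustment over 26 tests).

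Shorter steps along the C terminus separated the promoter classes. Removing residues 681-730 lowered 5 promoters in edgeR and raised 0 (317 at an unadjusted p under 0.05), while DESeq2 called 12 lower and 39 higher. Among the 5 were VHR2 (−2.40 ± 0.454, adjusted p = 0.00192), GNP1/SMT3 (−2.36 ± 0.416) and BAP3/HEM12 (−2.33 ± 0.407). Without Gln3(1-680) replicate A or B or intact replicate 1 the count was 3, and with RLE scaling 10. Of the permeases 4 of 10 permeases fell (7 adjusted over the list alone; estimated correlation 0.000618). In Gln3(1-630) 5 permeases fell, in Gln3(1-580) 6, with GNP1/SMT3 at −2.72, and in Gln3(1-530) 7. Without intact replicate 1 the calls over all promoters dropped from 9 to 2, from 37 to 6 and from 83 to 14, and without replicate 2 to 4, 9 and 20. Respiratory promoters fell in Gln3(1-530) at 6 of 42 (7 adjusted over the list alone; camera 2.07e-13, adjusted p = 0.0615 with an estimated correlation), and in Gln3(1-430) at 27 (31 adjusted over the list alone; 0.00124 with an estimated correlation). The share at the respiratory list was 4.22 ± 0.219% in intact Gln3, 6.10 ± 1.09% in Gln3(1-680), 4.23 ± 0.710% in Gln3(1-580), 2.30 ± 0.560% in Gln3(1-530) and 1.12 ± 0.0488% in Gln3(1-480). The permease share was 5.29 ± 0.500% in intact Gln3 and 1.54 ± 0.130% in Gln3(1-680). Internal deletions within 480-580 each lowered few promoters: COX13 (−2.11 ± 0.471, 0.0493) and PUT3/ATP7 (−2.09 ± 0.472) were among 3 lower in Gln3(1-530+580-730), and QCR10 (−2.06 ± 0.440, 0.0289) and ATP3 (−1.93 ± 0.382, 0.0148) were the 2 lower in Gln3(1-480+530-730). DESeq2 called 19 lower and 1 higher in the first, and 20 lower and 57 higher in the second. The respiratory list fell as a whole in both (19 adjusted over the list alone in each; 5.38e-05 and 0.00153 with an estimated correlation), but each of the 4 named calls ended without either library of its deletion, without either library of intact Gln3 and with the 400 bp window. That window also ended the call at VHR2.

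**Figure D1:**
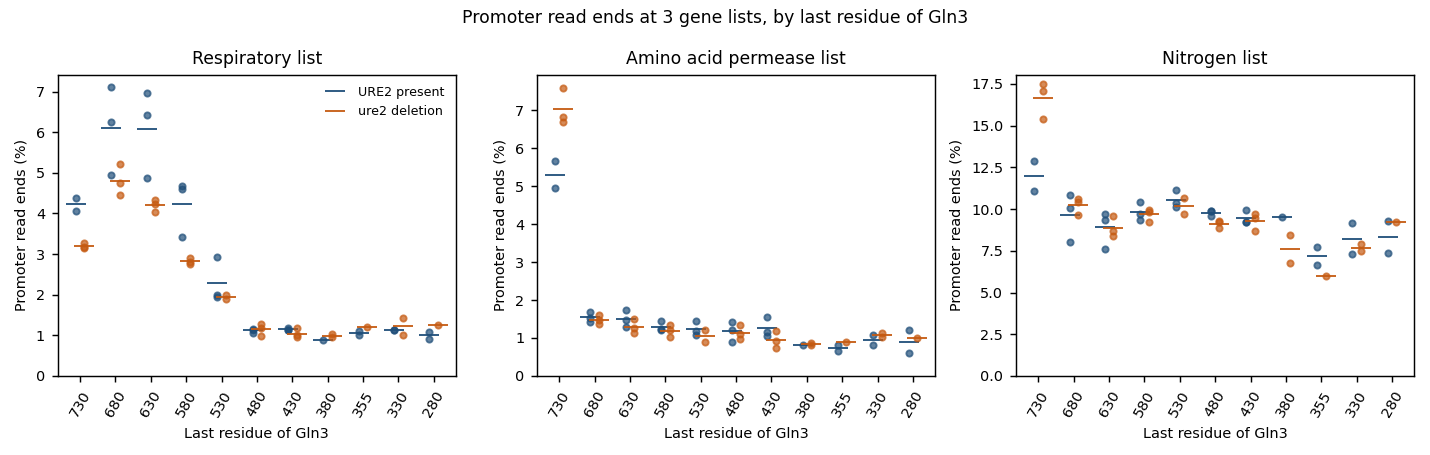
Share of promoter read ends (percent, vertical axis) at the respiratory, permease and nitrogen lists against the last residue kept in Gln3, with URE2 present and in the ure2 deletion. Points are libraries and dashes are group means; the respiratory share is 4.22% in intact Gln3 and 1.12% in Gln3(1-480), and the permease share is 5.29% and, in Gln3(1-680), 1.54%.

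N-terminal truncation was followed to residue 272. In Gln3(272-730) signal at GLN1 (XVI, 641508 to 642207, R64), the glutamine synthetase promoter and a main Gln3 target, fell from 15714 ± 639.7 to 1515 ± 362 CPM (−3.37 ± 0.399, adjusted p = 1.25e-08, n = 2 and 2), a call that each library left out and each setting kept. Higher signal was seen at ATP20 (2.84 ± 0.541, 0.00233), DAL2 (allantoin breakdown, 2.44 ± 0.536, 0.0203) and IDP1/COX9 (1.95 ± 0.448, 0.0249). Respiratory promoters rose at 4 of 42, including IDP1/COX9, and 12 were higher adjusted over the list alone (camera 6.38e-23), and their share was 7.81 ± 0.400% against 4.22 ± 0.219%. Of the nitrogen promoters 4 rose, including DAL1/DAL4 (1.75) and UGA4 (1.49), and 1 fell (7 and 3 adjusted over the list alone; 0.00209), while the permease list (0.0220) and the stress list (1 lower; 0.0121) were called at the preset correlation. For these 3 lists adjusted p = 0.550 with an estimated correlation. In all 18 promoters rose and 6 fell. With library size only 18 rose and 22 fell, with the median of all promoters at −0.15. With DESeq2 35 rose and 23 fell, with the cap 0 rose and 2 fell, and with only the compared groups 215 rose and 85 fell. Without replicate A or B of Gln3(272-730) the count of 24 fell to 4 and 3, and without replicate 1 or 2 of intact Gln3 to 1 and 1, so outside GLN1 no call named here held in every such fit or with the cap. Only ATP20 kept its call without either library of Gln3(272-730), and none did without either library of intact Gln3. Gln3(63-730) and Gln3(103-730) differed from intact Gln3 at 0 promoters in edgeR and in DESeq2 (15 and 29 in edgeR at an unadjusted p under 0.05), and GLN1 lay lower in the single library of Gln3(228-730), which has no spread of its own (−3.63; not called with the cap).

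Ure2 holds Gln3 back when nitrogen is plentiful, and its deletion was tested in intact and truncated Gln3. In intact Gln3 signal rose at DAL5 (allantoate permease, to 1662 ± 141 CPM, 2.64 ± 0.538, adjusted p = 0.00115, n = 3 and 2), GAP1 (general amino acid permease, 2.32) and PUT1 (proline oxidase, 2.50). It also rose at PUT4/CIN1 (2.14), YHL015W-A/DUR3 (2.22), NIT1 (2.10), GLN1 (1.29) and RPS20 (2.69 ± 0.414, 9.37e-06). So did the asparaginase copies ASP3-3 (2.99 ± 0.408, 1.44e-06) and ASP3-2 (2.71 ± 0.382), whose near-identical sequences make the separate values uncertain. Of the 52 nitrogen promoters 22 rose and 0 fell (36 adjusted over the list alone; camera 1.28e-28), and their share of promoter read ends was 16.7 ± 1.10% against 11.99 ± 1.30%, higher in 3 of 3 libraries than in both controls. The amino acid synthesis list also rose (2 higher, 10 adjusted over the list alone; 2.88e-05). The permeases (1 higher, 7 adjusted over the list alone; 5.90e-06), glycolysis (0 and 5; 4.54e-06), the stress list (2 and 9; 5.90e-06) and the respiratory list (0; 0.0378) were called at the preset correlation, with adjusted p = 0.0637, 0.0637, 0.161 and 0.548 with an estimated correlation. Ribosomal protein genes (3 higher; 0.299) were not called. In all 120 promoters rose and 0 fell (669 at an unadjusted p under 0.05, and 336 called by DESeq2). With RLE scaling (median of all promoters −0.32) 40 rose, with library size only (−0.77) 18 rose and 2 fell, with the cap 11 rose, and with only the compared groups 341 rose and 65 fell. Without ure2 deletion replicate B or C 37 and 53 were called, and without intact replicate 1 or 2 26 and 9. Without intact replicate 2 the calls at DAL5, GAP1, PUT4/CIN1, YHL015W-A/DUR3, NIT1 and GLN1 ended. Those at DAL5, PUT4/CIN1 and GLN1 also ended without intact replicate 1, and that at GLN1 without ure2 deletion replicate B or C. With the cap GAP1, PUT1, PUT4/CIN1 and YHL015W-A/DUR3 were not called and GLN1 was at −0.43. DAL5, NIT1, PUT4/CIN1 and GLN1 were not called with library size only.

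In Gln3(1-480) the ure2 deletion changed 0 promoters in edgeR (345 at an unadjusted p under 0.05, n = 3 and 3), and 5 rose and 9 fell in DESeq2. The nitrogen share was 9.12 ± 0.214% against 9.77 ± 0.167% (exact permutation p = 0.1, the smallest possible; 0.52 after adjustment). At the 120 promoters raised in intact Gln3, the median effect was 1.59 there and −0.05 in Gln3(1-480) (quartiles −0.34 and 0.25). The interaction of Ure2 with the truncation was called at 54 promoters, each with the larger effect in intact Gln3, and for the nitrogen list (camera 4.91e-24; estimated 0.00160). The ribosomal protein list was called higher (0.0128, with adjusted p = 0.808 with an estimated correlation), the nitrogen list was not (0.167), and the respiratory list (0.818) had a median and mean below 0 with a test direction above it. In the other lengths the median at these promoters was 0.40 in Gln3(1-680), 0.24 in Gln3(1-630) and 0.12 in Gln3(1-580), with 0, 3 and 15 called interactions, and PUT1 rose in Gln3(1-680) (1.55 ± 0.340, 0.0405), a call that ended without any 1 of its 6 libraries. In Gln3(1-280), with 1 library, which has no spread of its own, against 2, 65 promoters rose and 136 fell in the ure2 deletion; without replicate A or C of Gln3(1-280) 532 and 97 were called, and with only the compared groups 0. In the variant without the zinc finger stretch the ure2 deletion changed 0 promoters in edgeR and in DESeq2 (30 in edgeR at an unadjusted p under 0.05). In Gln3(1-480) 1 promoter was called without replicate C, 1 without ure2 deletion replicate A and 2 without its replicate C.

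Hap2 is the DNA-binding subunit of the CCAAT-box complex that activates respiratory genes, and its deletion tests whether Gln3 needs it at those promoters. Signal at TIM11 (IV, 1112294 to 1112479, R64) fell from 771 ± 17.1 to 28.7 ± 11.7 CPM (−4.65 ± 0.351, adjusted p = 1.45e-08, n = 2 and 2), and at COX5A from 972 ± 83.4 to 63.6 ± 14.8 CPM (−3.90 ± 0.327, 3.46e-08). The fall at ATP19 was −4.52 ± 0.444 (2.35e-07), at SDH3 −4.44 ± 0.525 (3.19e-06), at ATP15 −4.06 ± 0.313, at KGD4 −3.85 ± 0.368 and at UGA3/GLT1 −3.70 ± 0.387. Of 42 respiratory promoters 29 fell and 0 rose (34 adjusted over the list alone; camera 1.38e-112), including QCR10 (−3.57) and KGD1 (−3.11), and the list's share was 0.897 ± 0.001% against 4.22 ± 0.219%. Retrograde-response promoters fell at 2 of 7, one of them IDH2 (−2.01), with a mean below and a median above 0 (0.0470). Nitrogen promoters fell at 4, including GDH3 (−1.97), and rose at 3, including PUT4/CIN1 (1.63 ± 0.347, 0.00691) and GAP1 (1.16 ± 0.253, 0.00854; list 0.0470). Permeases rose at 2, BAP2 (1.35 ± 0.309) and TAT1 (1.21 ± 0.306; 4.67e-05), and stress promoters at 2 (4 adjusted over the list alone; 1.41e-05). Those lists had adjusted p = 0.224 (retrograde response), 0.354, 0.0684 and 0.224 with an estimated correlation. In all 80 promoters fell and 17 rose of 4419. Most lower promoters followed through the fits, though not all, held with each library left out, while those named as higher ended with the cap and in at least 1 other fit. These calls ended for PUT4/CIN1 without hap2 deletion replicate B or intact replicate 2, GAP1 without hap2 deletion replicate A or intact replicate 2, and BAP2 and TAT1 without any 1 of the 4 libraries. Without hap2 deletion replicate A 2 rose and 60 fell, without B 4 and 57, without intact replicate 1 8 and 62, and without 2 0 and 70. With the cap 3 rose and 61 fell, and with only the compared groups 41 rose and 127 fell.

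In Gln3(1-480) the hap2 deletion lowered 2 promoters, ODC1 (−2.23 ± 0.279, adjusted p = 0.000219) and INH1 (−1.67 ± 0.280, 0.0111); neither was called without replicate A of that deletion, with the cap or with only the compared groups, nor INH1 without replicate B of either side. At the 80 promoters lowered in intact Gln3 the median effect was −2.32 there and −0.34 in Gln3(1-480) (quartiles −0.64 and −0.02), whose median level there before the deletion, 197 CPM, was near the 139 CPM of intact Gln3 in the hap2 deletion. The interaction was called at 64 promoters, for 45 of them lower in intact Gln3. The respiratory list differed between the 2 settings (camera 7.03e-61; estimated 4.72e-06). The promoters lower in the hap2 deletion and those lower in Gln3(1-480) against Gln3(1-580), which have no library in common, numbered 80 and 81, and 64 were in both where 1.47 would be by independent draws.

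Gat1 is a second GATA activator of the nitrogen genes. In the gat1 deletion Gln3 signal rose at BAP2 (1.55 ± 0.311, adjusted p = 0.00804, n = 2 and 2), AGP1/KCC4 (1.27), GLN1 (1.30), GAP1 (1.07), MEP1/YGR121W-A (1.34), TAT1 (1.53) and the sodium pump promoter ENA1/RSM10 (1.94 ± 0.304, 0.00321). Nitrogen promoters rose at 11 of 51 (14 adjusted over the list alone; camera 7.29e-12), permeases at 7 of 10 (2.67e-10) and stress promoters at 6 (11 adjusted over the list alone; 6.18e-10, with adjusted p = 0.0599 with an estimated correlation). Glycolytic promoters rose at 2 (5.81e-07) and retrograde-response ones at 1 (0.00101). The respiratory list was called as a whole with no single call (1.11e-10). In all 137 promoters rose and 4 fell, among them RRP5/RPS10B (−1.54 ± 0.400, 0.0321). The rise depended on scaling and on single libraries. With library size only, which put the median of all promoters at −0.77 in place of −0.09, 0 rose and 3 fell, with the 400 bp window 48 were called, with the cap 2, and with only the compared groups 223 rose and 367 fell. Without gat1 deletion replicate A or B 5 and 21 were called, and without intact replicate 1 or 2 9 and 0. No promoter named as higher held in every fit or with library size only. ENA1/RSM10 was not called without intact replicate 2, GLN1 and TAT1 without either intact library or replicate A. GAP1 and MEP1/YGR121W-A were not called without intact replicate 2 or either replicate of the deletion, and BAP2, AGP1/KCC4 and RRP5/RPS10B without any 1 of the 4. In Gln3(1-480) the gat1 deletion changed 0 promoters in edgeR (135 at an unadjusted p under 0.05) and lowered 1 in DESeq2; the interaction was called at 7.

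Deletions of DAL81 and GCN4 were tested in intact Gln3. In the dal81 disruption BAP3/HEM12 (−4.33 ± 0.261, adjusted p = 1.99e-10), AGP1/KCC4 (−4.26 ± 0.286) and GNP1/SMT3 (−3.53 ± 0.291) fell, 9 of 10 permeases fell (10 adjusted over the list alone; camera 1.12e-67, estimated 4.37e-06), and the permease share was 0.739 ± 0.169% against 5.29 ± 0.500%. In all 23 promoters fell and 6 rose. DESeq2 called 31 lower and 36 higher. Without dal81 replicate A 149 fell and 37 rose, without intact replicate 1 13 fell and 1 rose, with the cap 19 were called and with only the compared groups 6. In the gcn4 deletion 0 promoters changed in edgeR (403 at an unadjusted p under 0.05), and 5 rose in DESeq2.

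A move from exponential growth in synthetic medium to a poor nitrogen source was tested in the ure2 deletion. After 60 min in proline, signal rose at PUT1, the first enzyme of proline use, from 1067 ± 257 to 4718 ± 164 CPM (2.14 ± 0.270, adjusted p = 6.60e-05, n = 2 and 3). It rose at LYS14 (2.76 ± 0.356, 6.60e-05), at the glucose transporter promoter HXT2 (1.96 ± 0.254) and at PGM2/YMR105W-A (2.37 ± 0.358, 0.000430). It fell at CTR1 (copper uptake, −4.24 ± 0.825, 0.00556), STR3 (−3.83 ± 0.842, 0.0138), the sulfate permease promoter SUL2 (−2.26 ± 0.454, 0.00643) and VAC17/CHA1 (−2.74 ± 0.459, 0.00143). Nitrogen promoters rose at 2, PUT1 and PTR2 (1.24), and fell at 8, including DAL3/MGA2 (−2.08), with 2 and 9 adjusted over the list alone (0.158). Stress promoters rose at 4 (5 higher and 4 lower adjusted over the list alone; 7.89e-05) and respiratory ones fell at 3, ATP3 (−2.06) among them (10 adjusted over the list alone; 3.11e-05), both with adjusted p = 0.455 with an estimated correlation. Ribosomal protein genes went both ways (2 and 2; 0.0513). In all 36 promoters rose and 40 fell of 4237, with a median of −0.16 over all; DESeq2 called 45 higher and 111 lower. The count of 76 fell to 24 without proline replicate A, 27 without replicate 15B and 38 without 25B of the synthetic medium, and to 47 with the 400 bp window and 48 with only the compared groups. CTR1 was not called without proline replicate B or control 25B, STR3 and SUL2 without control 15B and proline replicate A (STR3) or B (SUL2). VAC17/CHA1, PTR2 and ATP3 were not called without proline replicate A. DAL3/MGA2 was not called without that library or any 1 of the 3 controls, 15B, 25A and 25B, nor with RLE scaling, the 400 bp window or the cap. With ammonium 21 rose and 17 fell, LYS14 rising again (2.63 ± 0.354) and CHO2 falling (−3.02 ± 0.386); without glucose 8 rose, such as DIA1 (2.91 ± 0.494), and 24 fell; DIA1 was not called without replicate A in that medium. For the medium without glucose library size only gave 29 higher and 22 lower, so the balance rests on the scaling, DESeq2 gave 30 and 66, and the cap gave 14 calls. Leaving out replicate A or B of that medium gave 10 and 18 calls, and leaving out control 15B, 25A or 25B gave 20, 21 and 18. For ammonium these were 10 and 18, and 21, 24 and 22, with 65 in DESeq2, 19 with the 400 bp window, 15 with the cap and 25 with only the compared groups.

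Variants labelled A and D changed residues from a given start to the end of the protein, from the first residue to a given end, or both; the labels do not say what the letters stand for. Between Gln3(481-730)A and Gln3(481-730)D, signal was higher in A at MEP1/YGR121W-A (10749 ± 3374 against 172 ± 36.7 CPM, 5.95 ± 0.482, adjusted p = 5.13e-17, n = 5 and 2), AGP1/KCC4 (5.55 ± 0.483, 8.75e-16) and MEP3 (5.40 ± 0.483). It was also higher at NOC4/ASN1 (asparagine synthetase, 5.44 ± 0.476), DIP5 (5.05 ± 0.461), QCR9 (5.45 ± 0.438) and TIM11 (5.38 ± 0.485). It was lower at promoters such as YNR077C (−1.84 ± 0.313, 2.14e-06; not called with the 400 bp window). Nitrogen promoters rose at 42 of 52, including GAP1 (4.08) and GLN1 (4.01; 43 adjusted over the list alone; camera 4.14e-29), and respiratory ones at 38 of 42, including COX5A (4.98; 1.95e-35). Permeases rose at 8 of 10, including BAP2 (3.68; 9 adjusted over the list alone; 2.07e-12), and retrograde-response ones at 7 of 7, CIT2 (3.18) among them (3.57e-07). Stress (18; CTT1 3.61; 2.06e-09), amino acid synthesis (18; 0.000497) and glycolytic promoters (12; 2.18e-06) were also higher, with adjusted p = 0.0576, 0.145 and 0.133 with an estimated correlation; 5 ribosomal protein promoters rose in a list whose median, mean and test lay below 0 (0.294). In all 761 promoters rose and 251 fell. With RLE scaling (median of all promoters −0.18) 706 rose and 365 fell, and with library size only (−0.97) 336 rose and 1725 fell. With the replicate block 827 rose and 429 fell. How many rose and fell, and the balance between directions, therefore rest on the scaling and the model. Leaving out Gln3(481-730)D replicate 1 or 2 gave 139 and 106 lower, and leaving out A replicate 1 gave 153. Against intact Gln3, Gln3(481-730)A differed at 4 promoters, DAL5 higher (1.72 ± 0.347) and GLN1 lower (−1.81 ± 0.351) among them, both not called without either library of intact Gln3, and Gln3(481-730)D at 729 in sum, 627 of them lower, GLN1 (−5.81 ± 0.568) and AGP1/KCC4 (−5.63 ± 0.504) included. The balance of that count rests on the scaling: with library size only (median of all promoters 0.88) 896 rose and 293 fell. Without replicate 2 of Gln3(481-730)D 477 were called. The nitrogen share was 1.79 ± 0.110% in Gln3(481-730)D. Its 2 libraries had an r of 0.5183 with each other, and the shallower held 59637 promoter read ends. Promoters, 17.84% of the nuclear genome, held a mean of 11.59% of their read ends, mitochondrial and ribosomal ones included. Lists of most kinds were higher in A, so these calls do not single out 1 class of promoters.

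Other starting points followed. From residue 581, with a single D library, 103 were higher in A and 17 lower, and from 531 113 and 42. From 581 113 were higher and 79 lower with library size only. From 531 71 were called without A replicate 1 and 72 without D replicate 1, 2 of them lower. From residue 631, ATP3 (2.10 ± 0.306, adjusted p = 5.64e-06) and ATP18/TDA9 (2.23 ± 0.340) were higher in A than in D, and 24 respiratory promoters were higher (0.0165 with an estimated correlation). In all 170 rose and 27 fell from 631, but with library size only 11 rose and 203 fell, so the direction rests on the scaling. Without A replicate 1 30 were called, without A replicate 3 309, without D replicate 2 or 3 49 and 91, and with the cap 61. From residue 681 0 were called in edgeR and in DESeq2 (158 in edgeR at an unadjusted p under 0.05). From residues 431, 381 and 356 respiratory promoters were higher in A at 29, 30 (a single D library, with no spread of its own) and 28, with ATP20 at 4.27 ± 0.388 from 356. Stress promoters were lower in A at 14, 21 and 14, with HSP12/YFL015C at −4.06 from 381. Over all promoters the 513 calls from 431 fell to 278 without A replicate 2 and 294 without D replicate 2. The 419 from 356 fell to 199 and 273 without A replicate 1 or 2 and to 167, 45 of them lower, without D replicate 1. GLN1 was lower in A from 356 (−2.91 ± 0.478; not called with the cap). The nitrogen shares of Gln3(431-730)D, Gln3(381-730)D and Gln3(356-730)D were 12.7%, 12.1% and 12.6%. When residues 1-250 and 381-730 were both of the D kind, 23 of 27 stress promoters were higher than in intact Gln3 (camera 2.61e-17; estimated 0.0283), such as ALD3 (3.52 ± 0.403) and HSP12/YFL015C (4.02 ± 0.593), and ATP20 was lower (−3.98 ± 0.341). The stress share was 4.61 ± 0.110% against 1.37 ± 0.0556%. In the first 50, 100 and 150 residues A and D differed at 0 promoters in edgeR (167, 501 and 191 at an unadjusted p under 0.05; 0, 20 and 0 called by DESeq2), and in the first 250 at 22 in sum, with OPT2 higher in A (2.37 ± 0.398; not called without D replicate 2). That count was 2 without A replicate 1, 4 and 0 without D replicate 1 or 2, 78 in DESeq2, 81 with the replicate block and 150 with only the compared groups, and with library size only 17 were higher and 30 lower.

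**Figure D2:**
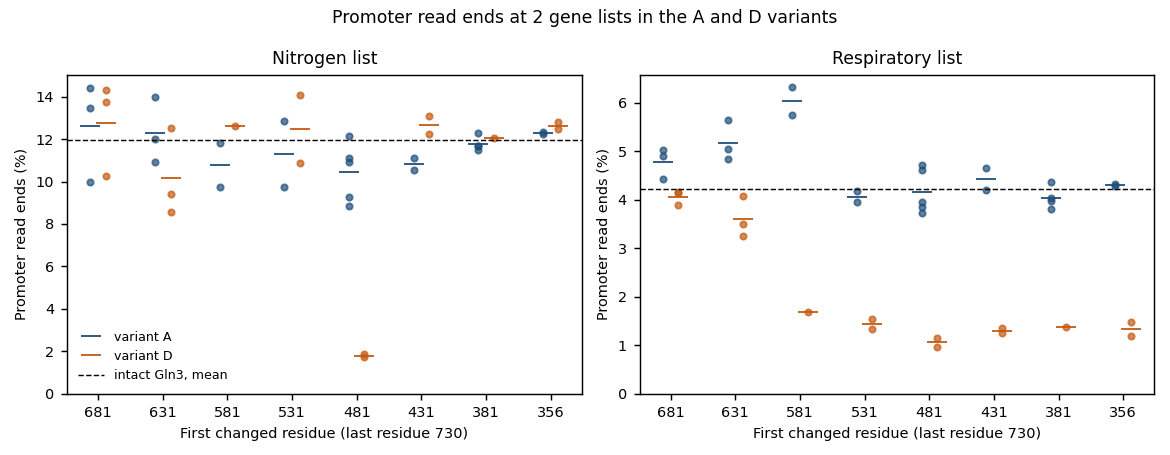
Share of promoter read ends (percent, vertical axis) at the nitrogen and respiratory lists in the A and D variants, by the first changed residue. Points are libraries and the dashed line is the mean of intact Gln3 (11.99% and 4.22%); Gln3(481-730)D lies at 1.79% for the nitrogen list.

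Gln3 genes from other yeasts were compared with the S. cerevisiae gene to ask how far binding is kept. Their genotypes carry a letter D after the species name that the labels do not explain. Few calls do not show that binding was kept: the simulated K. lactis comparison called 0% of 2-fold and 11% of 4-fold changes. The r between libraries of the same gene was 0.3434 to 0.5353 for lactis and 0.5269 for kluyveri. It was 0.813 to 0.9437 for mikatae, kudriavzevii and castelli. In the K. lactis orthologue GCN4/YEL008W rose from 1094 ± 12.5 to 4580 ± 1022 CPM (2.07 ± 0.356, adjusted p = 0.00735, n = 3 and 2), the 1 call (144 at an unadjusted p under 0.05, and 3 higher and 26 lower in DESeq2). The respiratory list (0 calls, 6 lower adjusted over the list alone; camera 5.58e-07), the nitrogen list (0, and 6 lower; 0.00160) and the permeases (0, and 2 lower; 0.000123) were below the others, with adjusted p = 0.406, 0.574 and 0.406 with an estimated correlation. The median of all promoters was −0.14, with RLE scaling 0.04 and with library size only 0.10. The call at GCN4/YEL008W ended without replicate 1 or 2 of intact Gln3, with the cap and with only the compared groups, and without lactis replicate A 1 rose and 38 fell. The genes labelled mikatae, kudriavzevii, castelli and kluyveri differed at 0 promoters in edgeR and in DESeq2 (9, 15, 34 and 102 in edgeR at an unadjusted p under 0.05), and kluyveri at 37 without its replicate A. The C. glabrata gene lowered 18 and raised 1, with ATP3 (−3.37 ± 0.588, 0.00399) and PUT3/ATP7 (−3.25; not called without its replicate B or intact replicate 1) lower and 9 of 42 respiratory promoters lower (25 adjusted over the list alone; estimated 0.0420). Its 2 libraries had an r of 0.4438 with each other. Without its replicate B 5 were called and without replicate C 509, 487 of them lower, and without intact replicate 1 or 2 5 and 9; the cap left 2 and the compared groups only 0, and DESeq2 called 45.

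In the second set, Gln3(1-380) was compared with the same protein without residues 101-280. GLN1 fell from 26629 ± 1616 to 2225 ± 796 CPM (−3.58 ± 0.527, adjusted p = 4.69e-05, n = 2 and 2). Signal also fell at SPG1 (−3.37 ± 0.568, 0.000292), the lactate dehydrogenase promoter CYB2 (−3.31 ± 0.619), ALD6 (−3.23 ± 0.602), CIT2 (−2.63) and PUT4/CIN1 (−1.58). It rose at SPT5/RAD33 (4.47 ± 0.839), SDH8 (4.22) and RAD14/ERG2 (5.63 ± 0.861, from 6.49 ± 9.18 to 206 ± 134 CPM). Stress promoters fell at 6 of 27, GSY1 (−2.46) and TSL1 (−2.14) among them (13 adjusted over the list alone; camera 4.87e-08). Nitrogen promoters fell at 8 and rose at 4 (10 and 5; 0.0231), the respiratory list was called with no single call (0.00734), and glycolytic promoters rose at 5 (0.0793). The first 3 had adjusted p = 0.371, 0.802 and 0.371 with an estimated correlation. In all 269 promoters rose and 186 fell. With only the compared groups 1 fell, GLN1, and 0 rose, so the other calls rest on the pooled spread of the wider group. With library size only 445 rose and 174 fell, with medians of all promoters of 0.42, 0.21 with RLE scaling and 0.13 in the main scaling, and DESeq2 called 712. Without replicate 1 of the shorter protein 300 rose and 638 fell, and without replicate 3, which also ended the calls at CIT2, GSY1, TSL1 and PUT4/CIN1, 138 rose and 26 fell; PUT4/CIN1 was not called without replicate 1 of Gln3(1-380) either. The genotypes of the versions of residues 101-280 with changed composition do not name the end at residue 380, which was read from their titles. In the version labelled dLIV GLN1 and SPG1 also fell (−4.42 ± 0.463 and −4.44 ± 0.503), while GLN1 was not called in those labelled dKR (0.01) and dM (−0.91).

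Within residues 481-580, Gln3(1-502+506-730), which lacks 3 residues, was compared with other short deletions in the same stretch, Gln3(1-481+485-730), Gln3(1-536+542-730) and Gln3(1-568+572-730). COX5A fell from 1192 ± 208 to 213 ± 46.9 CPM (−2.48 ± 0.389, adjusted p = 4.54e-06, n = 3 and 6). Signal also fell at ATP14/YLR296W (−2.43 ± 0.316, 5.59e-08), QCR6 (−2.40 ± 0.336, 4.19e-07), COX4 (−2.27 ± 0.379) and ATP15 (−2.26 ± 0.320). Of 42 respiratory promoters 30 fell (34 adjusted over the list alone; camera 7.84e-62), COX8 (−2.14), COX13 (−2.11) and SDH3 (−2.01) included, and their share was 1.80 ± 0.160% against 4.49 ± 0.330% (difference −2.69; two-sided exact permutation p = 0.0238, 0.0929 after adjustment, lower in 3 of 3). Nitrogen promoters fell at 3, UGA3/GLT1 (−2.23) and MEP3 (−1.45) among them (5 adjusted over the list alone; 3.44e-07, with adjusted p = 0.693 with an estimated correlation), and the permease list was not called (0.450). In all 76 fell and 42 rose, with a median over all promoters of 0.19; the rises rest on single libraries and on scaling. With RLE scaling (0.44) 68 rose and 64 fell, with library size only (0.48) 99 rose and 61 fell, and without replicate 3 of this deletion 5 rose and 30 fell and MEP3 was not called. COX4 was not called with the 400 bp window. Against intact Gln3 in the stp strains it lowered 55 promoters, and the other short deletions, in the order above, changed 0 in edgeR and in DESeq2 (208, 228 and 153 in edgeR at an unadjusted p under 0.05). These counts rest in part on 1 control library: without stp1 replicate 2 the other short deletions changed 73, 23 and 56, most of them higher, and Gln3(1-502+506-730) 188, 58 of them lower. It lowered 16 without its own replicate 3 and 32 without stp2 replicate 1, and Gln3(1-481+485-730) lowered 11 without its replicate 2. The versions of 481-580 with changed composition are named by their titles, since their genotypes give 481-280 for the stretch. Of these, those labelled dFWY, dM and dS changed 0 in edgeR (103, 224 and 142 at an unadjusted p under 0.05; 0, 0 and 5 called by DESeq2), and 42, 56 and 53 without stp1 replicate 2. The others lowered 12 to 31 respiratory promoters, counts that rest in part on single libraries, 30 of them in dKR, with YHR050W-A at −5.33 ± 0.604, and 31 in KR, with ATP19 at −3.21 ± 0.463. Over all promoters PG lowered 30, and 3 without its replicate 3, and NQT lowered 47, and 15 without its replicate 3. Without stp1 replicate 2 these versions had 116 to 353 calls, with 117 of 144 higher in PG and 262 of 353 in KR. A C. glabrata stretch in place of 481-580 changed 0 promoters in edgeR and in DESeq2 (127 in edgeR at an unadjusted p under 0.05) and 48 without that library. In place of 481-730 it lowered 89 and raised 31, with SEF1 at −3.67. That count dropped without its replicate 1. It was 65 without stp2 replicate 1, 348 without stp1 replicate 2 and 214 in DESeq2. C. glabrata stretches outside 481-580 also had effects: in place of 581-730 65 fell and 82 rose, and in place of 581-662 43 fell and 10 rose. The respiratory share was 1.80 ± 0.183% and 2.50 ± 0.186% in these, against 4.53 ± 0.0877% in the stp strains. Lower respiratory signal was therefore not confined to changes within 481-580.

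The hap2 deletion was also tested in Gln3(1-502+506-730), where much respiratory signal was already gone. TIM11 fell from 345 ± 111 to 28.6 ± 21.4 CPM (−3.40 ± 0.349, adjusted p = 1.08e-12, n = 6 and 3). Signal also fell at GDH3 (−3.11 ± 0.521, 7.56e-05), COX13 (−2.96 ± 0.320, 7.66e-12), KGD4 (−2.90 ± 0.350), KGD1 (−2.69 ± 0.275) and SDH3 (−2.57 ± 0.301). Respiratory promoters fell at 23 of 42 (27 adjusted over the list alone; camera 1.24e-71), KGD2/NUM1 (−2.42), COX5A (−2.13) and CIT1 (−2.14) included. Retrograde-response promoters fell at 3, including IDH1/NCE103 (−1.42; 7.57e-08), and nitrogen ones at 3, UGA3/GLT1 (−2.12) among them (5 adjusted over the list alone; 0.00801, with adjusted p = 0.599 with an estimated correlation). The respiratory share was 0.800 ± 0.116% against 1.80 ± 0.160% (exact permutation p = 0.0238, 0.0929 after adjustment). In all 61 promoters fell and 1 rose of 4421, 23 in sum with only the compared groups, UGA3/GLT1 not among them, and 36 without replicate 4 of Gln3(1-502+506-730). Gln3 without 481-580 and Gln3(1-502+506-730) differed at 0 promoters in edgeR and in DESeq2 when both lacked HAP2 (247 in edgeR at an unadjusted p under 0.05, n = 6 and 6).

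**Figure D3:**
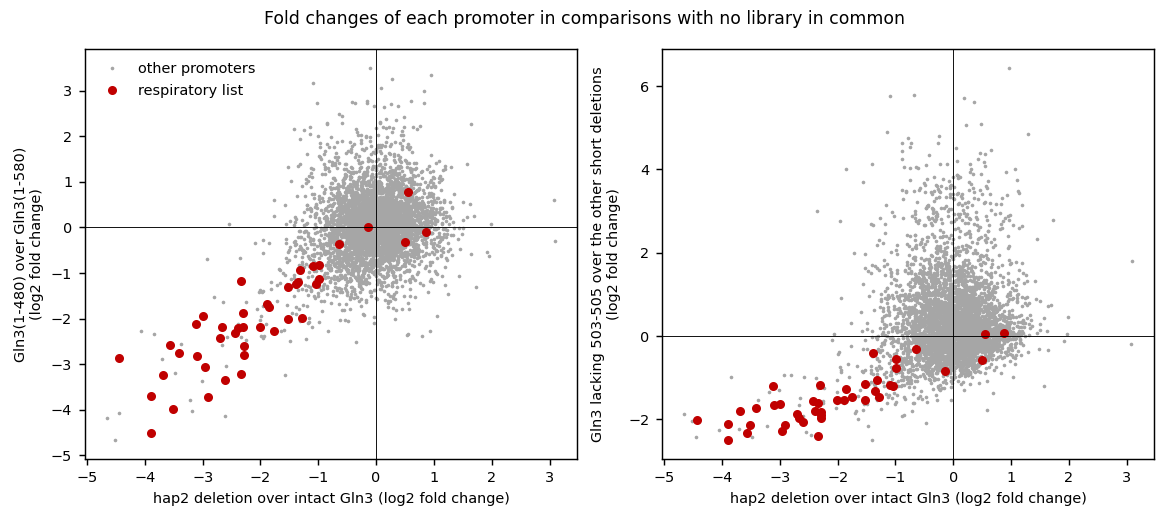
Log2 fold change of the hap2 deletion (horizontal axis) against that of Gln3(1-480) over Gln3(1-580) and of Gln3(1-502+506-730) over the other short deletions (vertical axes), 1 point per promoter with the respiratory list in red. Of 80 and 81 promoters lower in the first pair, 64 are in both.

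Hap3 and Hap5 are the partners of Hap2 in the CCAAT-box complex. Against the strains labelled stp1 and stp2 deletion, loss of HAP3 or HAP5 lowered TIM11 from 1205 ± 253 to 37.3 ± 16.6 CPM (−5.13 ± 0.373, adjusted p = 7.90e-17, n = 4 and 4), ATP19 (−5.56 ± 0.432, 6.67e-16), COX13 (−4.90 ± 0.369), COX8 (−4.64 ± 0.410) and COX5A (−4.37 ± 0.336). The promoters of glutamate metabolism UGA3/GLT1 and GDH1/YOR376W (glutamate dehydrogenase) fell (−4.30 ± 0.354 and −4.22 ± 0.330). Signal rose at QDR3 (2.50 ± 0.445, 7.52e-05), the peptide transporter promoter PTR2 (2.30 ± 0.420) and TAT1 (1.64 ± 0.283). Since the control strains are labelled as deletions of STP1 and STP2, activators of the permease promoters, these rises cannot be assigned to HAP3 or HAP5; PTR2 was also higher in the rtg1 deletion against them (2.36). Respiratory promoters fell at 37 of 42 (37 adjusted over the list alone; camera 4.49e-111), SDH3 (−4.19), CIT1 (−2.97) and IDP1/COX9 (−3.19) included, and their share was 0.889 ± 0.0258% against 4.53 ± 0.0877% (two-sided exact permutation p = 0.0286, the smallest possible, 0.0929 after adjustment). Retrograde-response promoters fell at 4, IDH2 (−2.26) among them (7.66e-07). Permeases rose at 2 (3 adjusted over the list alone; 0.00248), ribosomal protein promoters at 3 (0.000636), and nitrogen promoters fell at 7, such as GDH3 (−3.47) and MEP3 (−1.96; not called with the cap), and rose at 1 (0.000636), with adjusted p = 0.316, 0.261 and 0.662 with an estimated correlation. In all 173 promoters fell and 56 rose of 4412, with a median of 0.16. With library size only (0.43; 0.27 with RLE scaling) 144 rose and 124 fell, with DESeq2 102 rose and 187 fell, and with only the compared groups 11 rose and 134 fell. Without hap5 deletion replicate 2 152 were called, and without stp1 replicate 2 570 rose and 174 fell. The promoters lower here and in the hap2 deletion of the first set, which have no library in common, overlapped at 78 where 3.10 would by independent draws. The strains labelled stp1 and stp2 deletion differed from each other at 0 promoters in edgeR (419 at an unadjusted p under 0.05) and at 20 in DESeq2. That 0 rests on 1 library, since without stp1 replicate 2 582 were called, 538 of them lower; without stp1 replicate 1 or stp2 replicate 2 it was 2. In the rtg1 and rtg3 deletions, which lack the regulators of the retrograde response, CIT2 fell (−6.27 ± 0.346 and −5.85 ± 0.348; 4.35e-22 and 1.66e-20), as did DLD3 (−3.66 ± 0.280 and −3.85 ± 0.286).

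Hap2 itself was fused to MNase in the last part. Hap2(64-265), Hap2(1-77+132-265) and Hap2(1-221) were compared with full-length Hap2 in a gln3 deletion; since only the latter lacks GLN3, the comparison joins the truncation with the presence of Gln3. Signal was higher in the truncations at Gln3 targets: GLN1 rose from 463 ± 240.3 to 9583 ± 2939 CPM (4.34 ± 0.381, adjusted p = 1.11e-08, n = 6 and 3). GAP1 rose from 899 ± 144 to 11515 ± 5313 CPM (3.60 ± 0.319, 1.11e-08), AGP1/KCC4 by 3.36 ± 0.332 (9.66e-08), GDH2 by 3.74 ± 0.525 and MEP2/YNL143C by 3.34 ± 0.538. Signal fell at SDH2 (−1.98 ± 0.314, 0.000166), YHB1 (−2.08 ± 0.376; not called with the 400 bp window) and COX12 (−2.01). Nitrogen promoters rose at 21 of 52, PUT1 (2.63), DIP5 (2.12), MEP1/YGR121W-A (2.38) and PUT4/CIN1 (2.05) among them (26 adjusted over the list alone; camera 1.22e-31). Respiratory ones fell at 12 (19; 1.87e-22) and permeases rose at 2 (3; 4.91e-06), with adjusted p = 0.0673, 0.0698 and 0.312 with an estimated correlation. CIT2 rose (2.59). The nitrogen share was 12.6 ± 2.45% against 2.91 ± 0.187% (exact permutation p = 0.0238, 0.478 after adjustment). In all 54 promoters rose and 33 fell of 4410. With library size only (median of all promoters −0.12) 57 rose and 54 fell, with the cap, which ended the calls at SDH2, COX12 and DIP5, 53 rose and 1 fell. With libraries of at least 100000 promoter read ends 103 rose and 83 fell, and with only the compared groups 111 rose and 90 fell, while DESeq2 called 132. Without Hap2(1-77+132-265) replicate 2 53 were called, and without replicate 3 or 4 of full-length Hap2 40 and 56. Singly, the 3 truncations raised 32, 33 and 54 promoters and lowered 0, 0 and 40 (COX12 −4.01 ± 0.529 in Hap2(1-221)). Each left-out library reduced these totals. Pooled, 3 of 11 lower and 12 of 15 higher named promoters held with each library left out. Hap2 with the C. glabrata sequence raised GLN1 (4.29 ± 0.396) and GAP1 (4.20 ± 0.344). Gln3 strains whose labels also name a Hap2(1-221) fusion had higher signal at QDR3 (3.12 ± 0.496, 0.000535) than the stp strains, the same control as above. That comparison had 20 calls, 2 without replicate 2 of this group, 2 without stp2 replicate 2 and 436 without stp1 replicate 2.

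**Figure D4:**
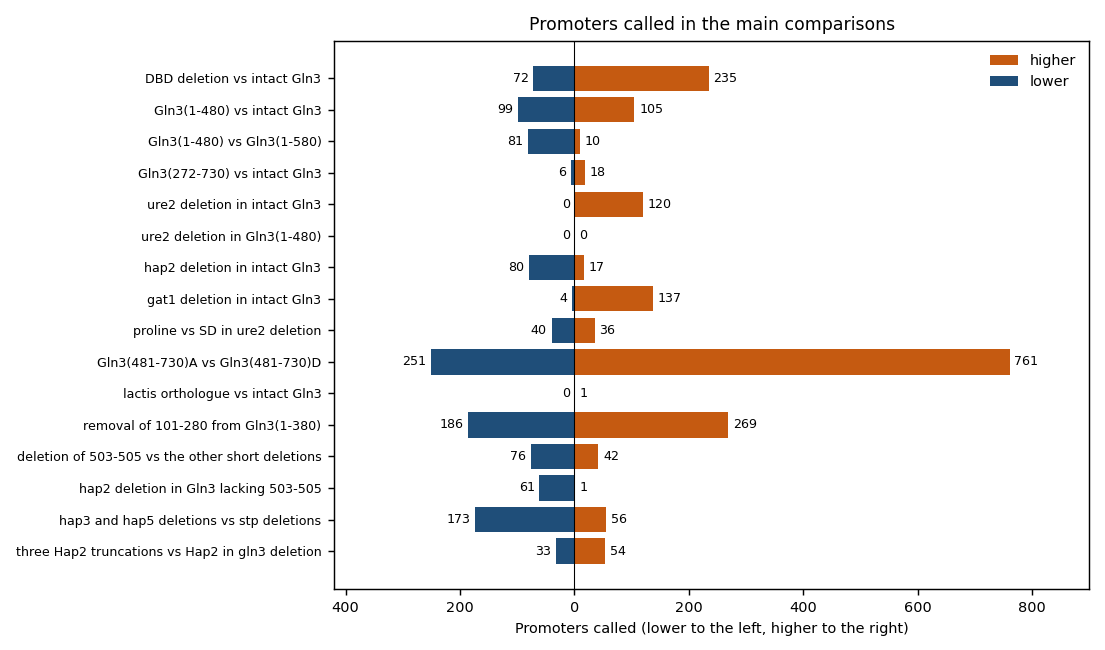
Number of promoters called higher and lower (bars) in each of the 16 main comparisons by edgeR at an adjusted p under 0.05 and a log2 fold change of at least 1 in size. Gln3(481-730)A against D has 761 higher and 251 lower, and the ure2 deletion in Gln3(1-480) has 0.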

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

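Of the tests of explanations below, the thinning of libraries was chosen before its result was seen, and all others, the counts over regroupings included, only after the results they address.

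The first pattern is the loss of respiratory promoters. In the hap2 deletion 80 promoters fell, with 29 of the 42 in the respiratory list among them, and 64 promoters had an effect of the deletion that differed between intact Gln3 and Gln3(1-480) in an interaction test. With library size only 90 promoters were lower. This cannot argue against scaling by a few strong promoters, which would make the others look lower in that setting. Scaling shifts all promoters of a library together, however, and their median was −0.005 where the 80 had −2.32. A common shift is therefore argued against for these 80. If promoters closed without Hap2, any MNase fusion would lose signal there. In Gln3(1-480) the median effect of the hap2 deletion at these 80 promoters was −0.3377, against −2.32 in intact Gln3, but the level of Gln3(1-480) there before the deletion (median 197 CPM) was already near that of intact Gln3 in the hap2 deletion (139 CPM; median log2 ratio 0.3975). Closed promoters therefore cannot be told apart from a need for Hap2, since little signal was left to lose. The overlap of 64 promoters with those lower in Gln3(1-480) against Gln3(1-580) is consistent with residues 481-580 and Hap2 acting at the same promoters, a hypothesis found and tested on the same data.

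The second pattern is the effect of the ure2 deletion, seen in intact Gln3 and not in Gln3(1-480). The interaction was called at 54 promoters for Gln3(1-480), 43 for Gln3(1-430), 20 for Gln3(1-380), 18 for Gln3(1-330), 15 for Gln3(1-580), 10 for Gln3(1-530), 4 for Gln3(1-355), 3 for Gln3(1-630), 0 for Gln3(1-680) and 19 for the variant without the zinc finger stretch. It was not tested for Gln3(1-280), where the ure2 deletion changed 201 promoters with 1 library against 2, and 0 with only the compared groups. Too little power in Gln3(1-480) would leave effects of like size without calls, but the median at the 120 promoters raised in intact Gln3 was −0.0481 there. Scaling may account for part of the 120, since 18 rose with library size only. The nitrogen share was 4.6799 percentage points higher in the ure2 deletion than in intact Gln3. That share is a sum relative to all promoter read ends, in which strong promoters such as GLN1 weigh most. With the cap GLN1 lay at −0.43, so the share does not settle how much of the rise rests on scaling or on few promoters. Each interaction uses the same 2 libraries of intact Gln3, so an error in these would appear in all of them, and that stays open.

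The third pattern is Gln3(481-730)D, which stands apart from intact Gln3 and from Gln3(481-730)A. Low depth is argued against: Gln3(481-730)A libraries thinned to 59637 read ends in 20 draws kept a median r with intact Gln3 of 0.7852, from 0.7444 to 0.7903, where the D libraries had 0.508. Variants with a D change over a longer stretch that includes 481-730 kept nitrogen shares of at least 12.062%. The D change of 481-730 thus did not lower that share in every form of the protein. These variants change further residues too, Gln3(381-730)D is a single library, and in each of them respiratory promoters were lower in D than in A. The D change of 481-730 as a source therefore stays open. A defect of this strain or its tag may be a source, and cannot be told apart from an effect of this very form of the protein, since no separately made strain is among the groups; the promoter share of its read ends was 11.5935%.

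In groups of 4 to 6 libraries, 5 of 52 tests placed 1 library far from its group, where chance does so in about 1 in 20. Replicate 2 of the hap2 deletion in Gln3(1-502+506-730) had an r with intact Gln3 of 0.525, where the other 5 had 0.7616 to 0.8682, and a respiratory share of 0.5695%, where they had 0.8162% to 0.8811%. The r of replicate 4 of the 101-280 version labelled NQT was 0.6124 (the others 0.8087 to 0.8315), that of Gln3(481-730)A replicate 2 was 0.8121 (0.9208 to 0.9477), and that of rtg3 deletion replicate 5 was 0.7769 (0.8974 to 0.9147). The gat1 deletion differed in effect between intact Gln3 and Gln3(1-480) at 7 promoters in an interaction test. Gln3(1-480+580-730), a single library in no comparison, had a nitrogen share of 14.9573%, above the 12.9014% of the higher intact library.

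Regrouping the same libraries, with fits of those libraries alone, was run for 26 counts. The shares of splits were not adjusted over these 26, and many of the comparisons use the same stp libraries. A regrouping cannot separate the labelled change from any other difference between the strains. Of the 84 splits 1, the real one, gave as many for Gln3(1-502+506-730) against the other short deletions (134, highest other 1). So it was for the hap2 deletion in it (23, 0) and for the Hap2 truncations (163, 1), shares under 0.05 before any adjustment. The same holds with 1 of 35 splits for hap3 and hap5 (157, 0), Gln3(1-502+506-730) against the stp strains (36, 0), the 481-580 versions dLIV (81, 1), dPG (89, 0), KR (70, 0), LIV (58, 0), NQT (47, 0) and PG (59, 7), and the C. glabrata stretches in place of 581-662 (60, 0) and 581-730 (90, 0). For the rtg3 deletion it was 1 of 100 drawn (109, 3), and for the rtg1 deletion 2 of 100, where another split gave 120 against the real 96. All 100 splits drawn gave as many as the 0 between Gln3 without 481-580 and Gln3(1-502+506-730) in the hap2 deletion (highest other 1). Where the real count is 0 every split gives as many, so such counts, here and below, could not be tested this way. With 3 libraries against 3, 10 splits are too few for a share under 0.05: the real and highest other counts were 70 and 0 for Gln3(1-480) against Gln3(1-580) (1 split as high), 150 and 0 for A against D from residue 631 (1), 43 and 1 for Hap2 of C. glabrata (1), 0 and 2 for A against D from 681 (10), and for the ure2 deletion 2 and 1 in Gln3(1-680) (1), 0 and 1 in Gln3(1-630) (10), 0 and 0 in Gln3(1-580) (10), 0 and 0 in Gln3(1-480) (10), 0 and 1 in Gln3(1-430) (10), and 1 and 1 in the variant without the zinc finger stretch (3).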

How the results depend on the processing

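The alternatives were fixed before testing, none was added later, and the cause of each shift below was not tested, except that a model of the compared groups only uses fewer samples by construction. Of the 16 main counts, moved means changed by over 1.5 times: DESeq2 moved 8, the cap 8, the compared groups only 11, library size only 5, the 400 bp window 2, RLE scaling 1, the depth minimum 1 of 15, and leaving out 1 library 40 of 95 fits. No fold threshold and no low-count filter moved 0 of 16, and the replicate block 0 of 5. Of the promoters named, leaving out 1 library ended 442 of 2203 calls and reversed none. The cap ended 88, the 400 bp window 50, the compared groups only 55, library size only 27, RLE scaling 3, no filter 0 and the depth minimum 11 of 345. DESeq2 kept all 371 and the block 118 of 119. Of 73 list calls, 46 were lost with the estimated correlation and 6 with library size only. The 400 bp window moved 56 of 87 list shares and correlations by more than their SD. The motif readout was not run, since no genome sequence was used. Groups of 1 or 2 libraries, and the 15 libraries with under 100000 promoter read ends, limit what could be called.

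With DESeq2 the counts were 326 for Gln3(1-480), 58 for Gln3(272-730), 336 for the ure2 deletion, 14 for it in Gln3(1-480), 156 for proline, 29 for K. lactis, 712 for the removal of 101-280 and 132 for the Hap2 truncations. RLE scaling gave 40 for the ure2 deletion. Library size only gave 40 for Gln3(272-730), 20 and 2 for the ure2 deletion in intact Gln3 and Gln3(1-480), 3 for gat1 and 2061 for A against D. With the cap they were 200 for the variant without the zinc finger stretch, 2 for Gln3(272-730), 11 and 1 for ure2, 64 for hap2, 2 for gat1, 0 for K. lactis and 54 for the Hap2 truncations. With the compared groups only they were, in the order of the report, 497, 300, 406, 168, 590, 48, 0, 1, 23, 145 and 201 (the variant without the zinc finger stretch, Gln3(272-730), ure2, hap2, gat1, proline, K. lactis, removal of 101-280, hap2 in Gln3(1-502+506-730), hap3 and hap5, Hap2 truncations). The 400 bp window gave 48 for gat1 and 47 for proline, and the depth minimum 186 for the Hap2 truncations.

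With 1 library left out, counts ran from 54 to 336 for the variant without the zinc finger stretch, 86 to 169 for Gln3(1-480), 58 to 169 against Gln3(1-580), 1 to 4 for Gln3(272-730), 9 to 138 and 0 to 2 for ure2 in intact Gln3 and Gln3(1-480), 61 to 70 for hap2, 0 to 21 for gat1, 24 to 75 for proline, 688 to 1057 for A against D, 0 to 39 for K. lactis, 164 to 938 for the removal of 101-280, 35 to 160 for Gln3(1-502+506-730), 36 to 84 for hap2 in it, 152 to 744 for hap3 and hap5, and 40 to 73 for the Hap2 truncations. Directions turned with the cap for IDP1/COX9 in Gln3(272-730) (−0.1342) and GLN1 in the ure2 deletion (−0.4342), with the 400 bp window for YPR148C in proline (−0.2244), and with library size only for the respiratory list in the ure2 deletion (adjusted p = 0.776935).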

Other observations

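Both hypotheses below were tested only after related results were seen.

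Hap2 fused to MNase in the gln3 deletion had a median of 1074 CPM at the 80 promoters where Gln3 lost signal without HAP2, at percentile 97.2 of all promoters, whose median was 104 CPM. Of the promoters lowered by the hap2 deletion, in Gln3(1-480) against Gln3(1-580), in Gln3(1-502+506-730) and by loss of HAP3 or HAP5, 52 were lower in all 4 comparisons. The 761 promoters higher in Gln3(481-730)A than in D, a count that rests on the scaling, and the 54 higher in the Hap2 truncations had 52 in common, against 9.32 by independent draws.

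Since amino acid permeases fell both in the dal81 disruption and in Gln3(1-680), residues 681-730 and Dal81 may act at the same promoters. In libraries used in neither comparison, Gln3(1-680) against intact Gln3 with both in the ure2 deletion, the 23 promoters lowered by the dal81 disruption had a median log2 fold change of −2.0197 (quartiles −2.774 and −1.7803), with 23 of 23 below 0 and 21 called lower, out of 42 called lower in that comparison, which is consistent with the hypothesis. A second hypothesis, that residues 481-580 joined to residues 273-380 could bring signal to the promoters lowered in Gln3(1-502+506-730), was left undecided. The median log2 ratio of the joined protein over Gln3(1-380) (n = 3 and 2) was 0.1673 at the 76 promoters (quartiles −0.8469 and 1.2337, 41 above 0). All promoters had a median of 0.4319. Over Gln3(272-480), a single library with no spread of its own, the medians were 0.7487 at the 76 and −0.0524 over all promoters.

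The unassigned libraries were 2. The title of the first names synthetic medium where its other labels name proline, and the title of the other names no deletion where its genotype names ure2; read ends per base over URE2 in this library were 0.437 of its nuclear mean.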
